A study of Mus musculus with 25 samples.

How the data were processed

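Expression was measured with a microarray of 72685 probe sets in lumbar dorsal root ganglia (L3 to L5) of male C57BL/6 mice. Of these, 6729 were control probe sets and 65956 were transcript probe sets. Samples were grouped by treatment and time as the labels give them, in 9 groups of naive, sham and DMM mice at 4, 8 and 16 weeks, with 25 arrays in all. The deposited values are log2 intensities, with 1 summary per probe set. The log2 scale is not stated and was read from the values, which ran from about 2.23 to 19.70 with array medians from 4.88 to 4.97. The authors' normalization between arrays, their summary method and their software are not given in the sources used here. The labels state biotin labelling by the manufacturer's standard protocol. For arrays there is no read depth, and the number of arrays limits the precision. The median residual SD was 0.121 on the log2 scale, and a 95% interval at the median moderated SD of limma reached 0.203 to each side for 3 arrays against 3 and 0.117 for the average over 3 times.

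Probe sets were named from the platform's own annotation, with symbols updated by their Entrez identifier in 827 cases. Of the transcript probe sets, 30604 carried exactly 1 symbol, 2146 carried several and 33206 had none, and those of the last 2 kinds were left out of the gene counts. Where a gene had more than 1 probe set (355 genes) the one with the highest mean over all arrays was used, which gave 30142 genes. Genes were kept when their mean over all arrays was above the 40th percentile of all probe set means (4.52), which left 20260. Over the 20260 genes kept, the correlation between arrays of a group was between 0.993 and 0.998.

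The deposited values were fitted in limma 3.58.1 (R 4.3.3) with 1 mean per group over all 25 arrays, so that the groups share 1 estimate of spread per gene, with 16 residual degrees of freedom. Contrasts were tested with the moderated statistic of eBayes and a constant prior (3.28 prior degrees of freedom), two-sided, and p-values were adjusted by Benjamini-Hochberg over the 20260 genes, with a threshold of 0.05. There were 12 comparisons: DMM against sham and DMM against naive at each of the 3 times, sham against naive at 4 and 16 weeks, naive mice at 16 against 4 weeks, DMM against naive averaged over the times, and the change of the DMM effect between 16 and 4 weeks against naive and against sham. The lone sham array at 8 weeks was assumed to vary like the other groups. The labels do not say that equal replicate numbers share anything, and the replicate number as a block was an alternative. Over the 21 pairs of arrays with equal numbers, the correlation of deviations from the group means ran from -0.359 to 0.318. It was over 0.1 in 8 pairs, 7 of them among the 9 pairs at 16 weeks. Sham and naive arrays at 16 weeks were the only groups in which all 3 pairs were over 0.1 (0.108 to 0.308). The numbers were treated as a possible pairing there, from the data and not from the labels. As these groups were picked on the same correlations, chance is not excluded.

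Before the data were examined, 40 gene lists were fixed from general knowledge, 22 of pathways and 18 of cell types that the tissue could hold. They held 832 entries, of which 736 matched a gene on the array. After first results had been seen, a fault in this matching was corrected: an old synonym had been used for symbols that are themselves current. Each list was tested with camera with a preset correlation of 0.01, with camera with an estimated correlation, and with fry in its directional form, adjusted over the 40 lists. Counts of list members are given over all genes tested and adjusted over the list alone. Genes were named by a rule fixed at the same time. It takes up to 10 genes higher and 10 lower of largest difference among those past the threshold with no overlap between groups (by chance 10% of genes do not overlap in 3 against 3). Where fewer than 10 pass, it adds the genes of smallest p as values, and it takes up to 4 members of each list described. It also takes 12 genes of pain and neuroimmune signalling in every DMM comparison. Predicted genes count in totals and are named outside the rule only where the text says so.

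The procedure was tested on simulated data, drawn per gene from a normal distribution with that gene's mean and residual SD, in which 100 genes were shifted by 0.5 and 100 by 1 on the log2 scale, up or down. For DMM against naive at 16 weeks it recovered 68 and 93 of them, with 9 unshifted genes called. For the averaged comparison it recovered 96 and 100, with 13 unshifted genes called. A macrophage list shifted by 0.3 had an adjusted p of 5.49e-10 with the preset and 0.000125 with the estimated correlation, and 0 of the other lists that share no member with it were called. Genes were drawn independently of each other. The simulation therefore does not show how often the preset test makes false calls where genes of a list move together.

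The alternatives tried were no filter on dim probe sets, a filter at the 60th percentile (5.52), cyclic loess and quantile normalization across the arrays, a fit of only the arrays compared, the replicate number as a block, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, all probe sets, an unadjusted p under 0.05 with a 1.5-fold difference, and each array left out in turn. Added after the data were seen were a covariate of array quality (positive minus negative control probe sets, from 5.75 to 6.08 on the log2 scale), a covariate of the mean of the nerve injury response list, and the leaving out of single arrays for the gene lists. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.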

Results

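Gene expression was measured on 25 microarrays of lumbar dorsal root ganglia (L3 to L5), which hold the cell bodies of the sensory neurons that serve the hind limb. The mice were male C57BL/6. They were untreated (naive), or had sham surgery or destabilization of the medial meniscus (DMM), a surgical model of knee osteoarthritis, in the right knee when 10 weeks old. Tissue was taken 4, 8 or 16 weeks after surgery, at 14, 18 or 26 weeks of age, and naive mice were taken at the same ages. Each of 8 groups held 3 arrays. The sham group at 8 weeks held 1 array, because the other samples of that group did not meet the submitters' quality control. Values are deposited log2 intensities, and 20260 genes had a mean above the brightness limit of 4.52 and were tested. That limit lies below the array medians of the negative control probe sets (5.06 to 5.35). It lies above those of the background probe sets (3.31 to 3.58). A gene that was tested may therefore lie at the level of the negative controls. Array medians lay between 4.88 and 4.97 on the log2 scale. The labels do not say how many animals each array holds, so each p-value measures the spread between samples. All errors beside a mean are SD between arrays, and errors beside a log2 difference are standard errors.

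DMM against naive mice, averaged over the 3 times, asks which genes differ in mice with surgery that destabilizes the knee. The clearest group was the circadian clock. Arntl, the transcription factor BMAL1 that drives the clock, rose by 1.04 ± 0.07 on the log2 scale, or 2.06-fold (adjusted p = 8.37e-08). Genes that the clock switches on in the opposite phase fell. Dbp, a clock-controlled transcription factor, fell by 1.44 ± 0.12 (adjusted p = 4.89e-06), Per3 fell by 0.84 ± 0.10 (adjusted p = 0.000317) and Per2 fell by 0.69 ± 0.07 (adjusted p = 8.38e-05). For these 4 genes every DMM array lay on the same side of every naive array of its own time. Nr1d1, the clock repressor REV-ERB alpha, fell by 1.003 ± 0.157 (adjusted p = 0.0112), with overlapping groups.

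Arntl stood at 7.30 ± 0.18 in DMM, 6.58 ± 0.10 in sham and 6.36 ± 0.23 in naive mice at 4 weeks (n = 3 each). At 16 weeks it stood at 7.11 ± 0.22, 6.19 ± 0.15 and 5.94 ± 0.10 in DMM, sham and naive mice (n = 3 each). The lone sham array at 8 weeks read 5.93, beside 6.96 ± 0.10 in DMM and 5.93 ± 0.05 in naive mice (n = 3 each). Dbp was 7.89 ± 0.20 in DMM and 9.55 ± 0.29 in naive mice at 4 weeks, and 8.54 ± 0.29 and 9.74 ± 0.21 at 16 weeks (n = 3 each). Sham mice differed from naive mice by -0.63 ± 0.22 in Dbp at 4 weeks (limma adjusted p = 0.16). In DMM against sham mice Dbp differed by -1.03 ± 0.22 at 4 weeks and -1.18 ± 0.22 at 16 weeks (limma adjusted p = 0.392 and 0.285). Of the 16 measured members of the circadian clock list, 1 rose and 4 fell over all genes tested, and 2 rose and 10 fell when adjusted over the list alone. The list's median was -0.30 (camera adjusted p = 2.90e-07 with the preset correlation). The same list had adjusted p = 0.0522 with an estimated correlation, and fry gave adjusted p = 0.00375. The labels give no time of day for tissue collection.

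**Figure D1:**
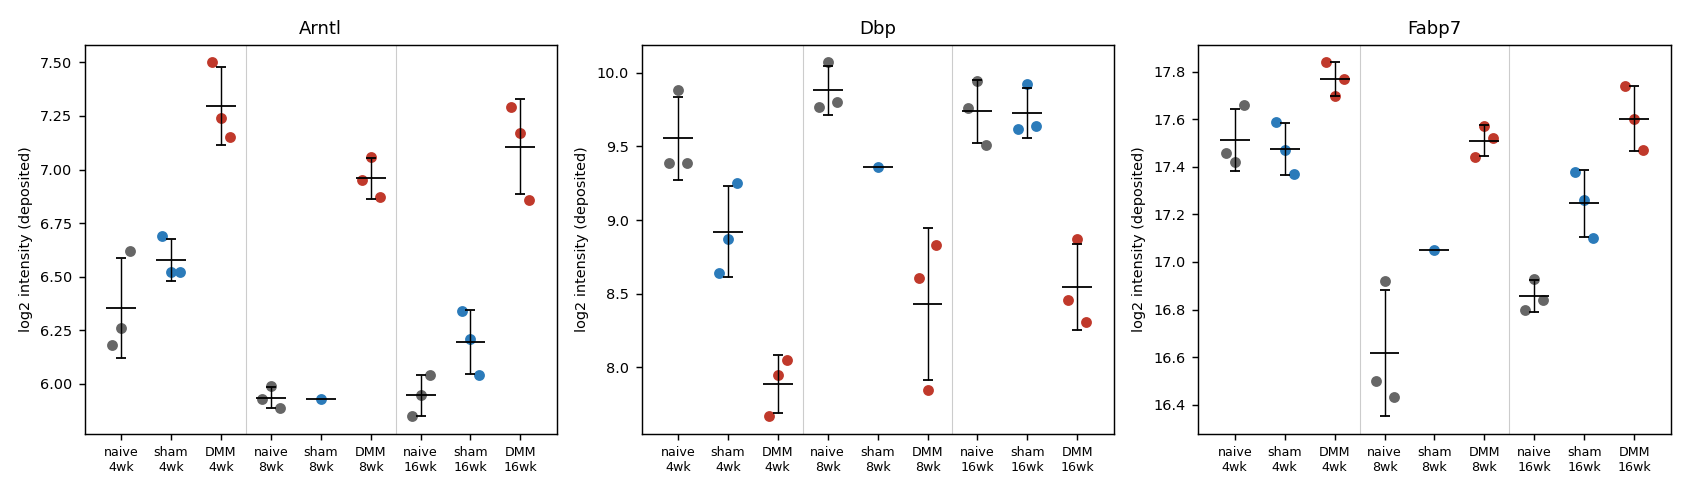
Log2 intensity of Arntl, Dbp and Fabp7 (vertical axes, which do not start at 0) in each array, by group and week. Points are arrays, long bars are group means and whiskers are SD (n = 3, except 1 sham array at 8 weeks). Mean Arntl was between 6.96 and 7.30 in DMM groups and between 5.93 and 6.36 in naive groups.

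Outside the clock list, Fabp7 rose by 0.63 ± 0.06 in DMM over naive mice (adjusted p = 2.88e-05). Whether Fabp7 moves with the clock or with time of day was not tested. Fabp7 is a fatty acid binding protein that marks satellite glia, the cells that wrap sensory neuron bodies. It stood at 17.77 ± 0.07 in DMM and 17.51 ± 0.13 in naive mice at 4 weeks, 17.51 ± 0.07 and 16.61 ± 0.27 at 8 weeks, and 17.60 ± 0.13 and 16.86 ± 0.06 at 16 weeks (n = 3 each). The 14 measured satellite glia markers, Fabp7 among them, had a median of -0.02 and a camera adjusted p of 0.781, and Fabp7 alone of them passed. Sat1, which breaks down polyamines, rose by 0.38 ± 0.05 (adjusted p = 0.00425). For Fabp7 and Sat1 every DMM array lay above every naive array of its time. Fam107a, a glucocorticoid-responsive actin regulator, fell by 0.40 ± 0.07 (adjusted p = 0.0343), and Foxi1, a transcription factor, fell by 0.26 ± 0.05 (adjusted p = 0.0371). As sets, macrophage markers had a median of 0.12, with 0 past over all genes and 2 higher adjusted over the list alone (camera adjusted p = 3.94e-06, adjusted p = 0.280 with an estimated correlation). This average pools opposite directions. The list mean was lower in DMM than in naive mice at 4 weeks (6.842 and 7.001). It was higher at 8 weeks (6.776 and 6.588) and at 16 weeks (6.85 and 6.456). Extracellular matrix genes had a median of 0.11 (camera adjusted p = 0.00116, adjusted p = 0.716 with an estimated correlation), and without DMM replicate 2 at 16 weeks their camera adjusted p was 0.245. The 9 genes named, 3 higher and 6 lower, were all that passed, and 1484 genes had an unadjusted p under 0.05 where chance gives 1013. Fam107a was lost in 16 of 23 alternative settings (adjusted p up to 0.101) and Foxi1 in 15 of 23 (up to 0.146). Without DMM replicate 3 at 16 weeks 26 genes passed, and Nr1d1 reached adjusted p = 0.0729 in the fit of only the arrays compared.

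At 16 weeks, DMM against naive mice showed a shift of the macrophage list as a set, beside single genes that included Arntl. Arntl rose by 1.17 ± 0.12 (adjusted p = 0.000153), Fabp7 by 0.75 ± 0.11 (adjusted p = 0.0146) and Lyz1, a lysozyme, by 0.92 ± 0.14 (adjusted p = 0.0290), with every DMM array above every naive array. The 19 measured macrophage markers were all higher, with a median of 0.35 (camera adjusted p = 5.28e-12). The set stayed past the threshold, at adjusted p = 0.0438 with an estimated correlation, and fry gave adjusted p = 0.00503. None of the 19 passed over all genes in limma, and 10 rose when adjusted over the list alone. Lyz2, the main macrophage lysozyme, stood at 11.75 ± 0.17 in DMM and 10.58 ± 0.22 in naive mice (n = 3 each, difference 1.16, adjusted p = 0.0629). Whether the Lyz1 probe set also reads Lyz2 was not tested. Csf1r, the receptor that keeps macrophages alive, differed by 0.53 ± 0.11 (adjusted p = 0.113).

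The alarmin and pattern receptor list, which holds sensors and danger signals of innate immunity, was the other set past the threshold under both correlations. Its median was 0.33 over 16 members (camera adjusted p = 3.30e-05, and adjusted p = 0.0213 with an estimated correlation). No member passed over all genes, and 2 rose adjusted over the list alone; Clec7a, a receptor for fungal glucans, differed by 0.58 ± 0.17 (adjusted p = 0.395). All 29 measured interferon-stimulated genes were higher, with a median of 0.41 (camera adjusted p = 7.15e-09, and adjusted p = 0.515 with an estimated correlation). None of them passed over all genes and 3 did adjusted over the list alone; Bst2, an antiviral tether, differed by 1.32 ± 0.28 (adjusted p = 0.113). One array carried much of this: the mean of the list was 7.98 in DMM replicate 3 and 6.97 and 7.24 in the other DMM arrays, and without replicate 3 the list had a camera adjusted p of 0.215. Class II antigen presentation genes had a median of 0.39 (camera adjusted p = 3.30e-05, 0 members over all genes and 5 adjusted over the list alone). It had adjusted p = 0.226 with an estimated correlation.

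Fibroblast and meningeal markers, from the sheath around the ganglion, moved with these sets: all 19 were higher, with a median of 0.49 (camera adjusted p = 1.38e-05). The set had adjusted p = 0.515 with an estimated correlation, and without DMM replicate 2 the camera adjusted p was 0.206. Slc6a13, a meningeal transporter, was 9.14 ± 1.62 in DMM and 7.21 ± 0.20 in naive mice (n = 3 each, adjusted p = 0.398). Neutrophil and marrow precursor markers, which share S100a8 and S100a9 with the alarmin list, were higher in 10 of 11 cases with a median of 0.32 (camera adjusted p = 0.00157, adjusted p = 0.515 with an estimated correlation). Extracellular matrix genes had a median of 0.33 (camera adjusted p = 4.06e-06, adjusted p = 0.515 with an estimated correlation), and without DMM replicate 2 the camera adjusted p was 0.262. Sensory neuron markers had a median of -0.01 (camera adjusted p = 0.362). In all, 3 genes passed and 1785 had an unadjusted p under 0.05. Lyz1 was lost in 8 of 11 alternative settings and Fabp7 in 4 of 11 (adjusted p up to 0.272 for each). Without DMM replicate 3 the count was 325, and it was 1 without DMM replicate 1, naive replicate 1 or naive replicate 3, 5 without DMM replicate 2, and 0 in a fit of only the arrays compared.

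**Figure D2:**
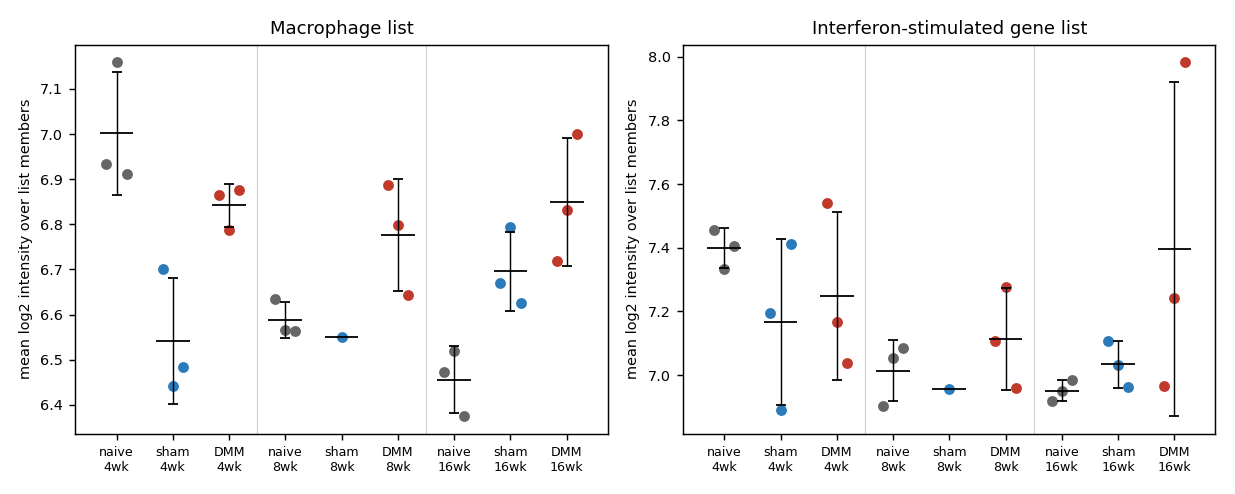
Mean log2 intensity over the 19 macrophage markers and over the 29 interferon-stimulated genes (vertical axes, which do not start at 0) in each array, by group and week. Points are arrays, long bars are group means and whiskers are SD (n = 3, except 1 sham array at 8 weeks). At 16 weeks the macrophage mean was 6.46 ± 0.07 in naive, 6.70 ± 0.09 in sham and 6.85 ± 0.14 in DMM arrays.

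At 8 weeks, DMM against naive mice again showed the clock genes apart. Arntl rose by 1.03 ± 0.12 (adjusted p = 0.00101), Per2 fell by 0.97 ± 0.13 (adjusted p = 0.00248), Dbp fell by 1.45 ± 0.22 (adjusted p = 0.0102) and Per3 fell by 1.09 ± 0.17 (adjusted p = 0.0187). Fabp7 rose by 0.89 ± 0.11 (adjusted p = 0.00101). A pair of ribosomal protein pseudogenes, Rpl35a-ps5 and Rpl35a-ps2, fell by 0.62 ± 0.11 and 0.57 ± 0.10 (adjusted p = 0.0405 and 0.0425). For these 7 genes no DMM array overlapped the naive arrays. The circadian clock list had a median of -0.35, with 1 member up and 3 down over all genes and 2 up and 7 down adjusted over the list alone. Its camera adjusted p was 4.14e-05, with adjusted p = 0.241 with an estimated correlation and a fry adjusted p of 0.0396.

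Myelinating Schwann cell markers were lower at 8 weeks in 14 of 15 cases, with a median of -0.29 and 0 past over all genes and 1 lower adjusted over the list alone (camera adjusted p = 1.22e-05, adjusted p = 0.452 with an estimated correlation). Pmp2, a myelin lipid carrier, was 9.17 ± 0.70 in DMM and 10.73 ± 0.51 in naive mice (n = 3 each, adjusted p = 0.205). Nerve injury response genes were higher in 22 of 23 cases, with a median of 0.27 (camera adjusted p = 4.14e-05). This was adjusted p = 0.452 with an estimated correlation, and the camera adjusted p was 0.842 without DMM replicate 2, whose list mean was 9.64 beside 8.27 and 8.60. Macrophage markers had a median of 0.21, with 0 over all genes and 1 up and 1 down adjusted over the list alone (camera adjusted p = 0.00366, adjusted p = 0.452 with an estimated correlation). In all 10 genes passed, 2 higher and 8 lower, and 1720 had an unadjusted p under 0.05. The other 3, Gm12109, Gm7931 and Gm9009, were named after their values were seen. The count was 120 without naive replicate 3 and 94 without DMM replicate 1. It was 5 without naive replicate 2, 4 without naive replicate 1 and 0 in a fit of only the arrays compared. Per3 was lost without naive replicate 1 or 2 or DMM replicate 2 (adjusted p = 0.17, 0.0777 and 0.0671), and Dbp without naive replicate 2 (0.0777). Rpl35a-ps5 and Rpl35a-ps2 were lost under cyclic loess (adjusted p = 0.0638 and 0.0560) and the replicate block (0.0727 and 0.0695). They were also lost with the nerve injury covariate and without naive replicate 1 or 2 or DMM replicate 2 or 3 (adjusted p up to 0.246).

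At 4 weeks, DMM against naive mice showed a pair of genes past the threshold, both of the clock. Arntl rose by 0.94 ± 0.12 and Dbp fell by 1.66 ± 0.22 (adjusted p = 0.00304 for each), with no overlap between the groups. Over the clock list the median was -0.39, with 1 up and 1 down over all genes and 2 up and 8 down adjusted over the list alone (camera adjusted p = 0.0107, adjusted p = 0.660 with an estimated correlation). Immediate early genes, which respond within minutes to stimulation, were higher in 16 of 20 cases with a median of 0.29 (camera adjusted p = 5.33e-10). That list had adjusted p = 0.525 with an estimated correlation, 0 members over all genes and 5 adjusted over the list alone. The list mean ran from 6.809 to 7.56 in DMM arrays and from 6.835 to 6.966 in naive arrays. The lowest DMM array thus lay below all naive arrays. Egr1, a transcription factor of the list, was 7.03 ± 0.71 in DMM and 5.86 ± 0.14 in naive mice (n = 3 each, adjusted p = 0.133). Nerve injury response genes were lower in 22 of 23 cases, with a median of -0.42 (camera adjusted p = 4.83e-06, adjusted p = 0.738 with an estimated correlation). Cell cycle genes had a median of -0.19, with 0 over all genes and 3 lower adjusted over the list alone (camera adjusted p = 4.01e-06, adjusted p = 0.660 with an estimated correlation). Macrophage markers were lower in 17 of 19 cases, with a median of -0.14 (camera adjusted p = 0.0192, adjusted p = 0.738 with an estimated correlation), and the camera adjusted p was 0.771 without naive replicate 2, 0.0595 without DMM replicate 1 and 0.136 without DMM replicate 2. In all 1783 genes had an unadjusted p under 0.05; 4 genes passed without DMM replicate 3 and 0 in a fit of only the arrays compared, and the clock list had a camera adjusted p of 0.0670 without naive replicate 2 and 0.0752 without DMM replicate 1.

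DMM against sham surgery asks what the joint lesion adds to the operation itself. At 16 weeks, Arntl was the single gene past the threshold, and it rose by 0.92 ± 0.12, or 1.89-fold (adjusted p = 0.00646), with every DMM array above every sham array. Dbp stood at 8.54 ± 0.29 in DMM and 9.73 ± 0.17 in sham mice (n = 3 each, difference -1.18, adjusted p = 0.285). The metallothioneins Mt2 and Mt1, metal-binding proteins of the glucocorticoid response list, differed by -0.83 ± 0.18 and -0.52 ± 0.13 (adjusted p = 0.601 for each). That list had a median of -0.20, with 0 over all genes and 3 lower adjusted over the list alone (camera adjusted p = 0.000536, adjusted p = 0.728 with an estimated correlation). It shares Per1 with the clock list. Interferon-stimulated genes were higher in 28 of 29 cases with a median of 0.29, though 0 members passed over all genes or adjusted over the list alone (camera adjusted p = 3.12e-11, adjusted p = 0.728 with an estimated correlation). Macrophage markers had a median of 0.14 (camera adjusted p = 0.000538, adjusted p = 0.728 with an estimated correlation). Extracellular matrix genes were higher in 26 of 30 cases with a median of 0.17 (camera adjusted p = 0.000614, adjusted p = 0.963 with an estimated correlation), and the fibroblast and meningeal list had a median of 0.07 (camera adjusted p = 0.0895). Without DMM replicate 2 the matrix list turned direction (camera adjusted p = 0.965).

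In this comparison 1306 genes had an unadjusted p under 0.05. Arntl was lost without sham replicate 2 or 3 or DMM replicate 1 or 2 (adjusted p between 0.0550 and 0.105) and with only the arrays compared (adjusted p = 0.835), while without DMM replicate 3 there were 11 genes. Without that DMM replicate 3 the camera adjusted p was 0.259 for the interferon list, 0.211 for the glucocorticoid list and 0.211 for the macrophage list.

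At 4 weeks, no gene passed between DMM and sham mice in limma, and 949 had an unadjusted p under 0.05. Arntl had the smallest p, at 0.72 ± 0.12 (adjusted p = 0.0864). Immediate early genes were higher in 19 of 20 cases, with a median of 0.36, and 9 rose when adjusted over the list alone beside 0 over all genes (camera adjusted p = 7.86e-12). The same list had adjusted p = 0.159 with an estimated correlation. Its mean ran from 6.809 to 7.56 in DMM arrays and from 6.721 to 6.95 in sham arrays. The lowest DMM array thus lay within the sham range. Egr1 was 7.03 ± 0.71 in DMM and 5.93 ± 0.13 in sham mice, and Ier2 was 5.23 ± 0.32 and 4.57 ± 0.30 (n = 3 each, adjusted p = 0.380 for both). The Ier2 mean in sham mice lay below the negative control medians of all arrays. Macrophage markers were higher in 18 of 19 cases with a median of 0.29, 0 past over all genes and 6 higher adjusted over the list alone (camera adjusted p = 5.04e-10, adjusted p = 0.159 with an estimated correlation). Fibroblast and meningeal markers were higher beside them in 19 of 19 cases, with a median of 0.53 (camera adjusted p = 7.60e-05, adjusted p = 0.634 with an estimated correlation). C1qc, a complement subunit made by macrophages, differed by 0.59 ± 0.15 (adjusted p = 0.831). Pain ion channels, the channels through which sensory neurons detect and conduct painful stimuli, had a median of -0.11, with 24 of 27 lower and 0 past over all genes or adjusted over the list alone (camera adjusted p = 0.000874, adjusted p = 0.496 with an estimated correlation). The gene count was 2 without DMM replicate 3 and 1 without DMM replicate 2, and the ion channel list had a camera adjusted p of 0.157 without sham replicate 2 and 0.0821 without DMM replicate 3.

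At 8 weeks, DMM was compared with 1 sham array, whose own spread is unknown and was taken from the other groups. No gene passed in limma, and 1708 had an unadjusted p under 0.05. Rnf5, a ubiquitin ligase, and Arntl had the smallest p, at 0.48 ± 0.08 and 1.03 ± 0.17 (adjusted p = 0.0530 for each). Toll-like receptor signalling genes had a median of 0.15, with 0 past over all genes and 2 higher adjusted over the list alone (camera adjusted p = 0.00268, adjusted p = 0.603 with an estimated correlation). Their adaptor Ticam1, also called TRIF, differed by 0.73 ± 0.15 (adjusted p = 0.176). Nerve injury response genes had a median of -0.28 (camera adjusted p = 0.00695, adjusted p = 0.737 with an estimated correlation), where the sham array read 9.38 for the list mean. That list had a camera adjusted p of 0.299 without DMM replicate 1 and 0.125 without DMM replicate 3. Macrophage markers had a median of 0.22 (camera adjusted p = 0.0110, adjusted p = 0.737 with an estimated correlation) and fibroblast and meningeal markers one of 0.38 (camera adjusted p = 0.0435, adjusted p = 0.786 with an estimated correlation). The fibroblast list had a camera adjusted p of 0.149 without DMM replicate 1 and 0.447 without DMM replicate 3. Under cyclic loess 3 genes passed, Arntl and Rnf5 among them (adjusted p = 0.0409 for each).

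Genes of the neuroimmune and pain pathways fixed for naming in every DMM comparison did not pass the threshold. Over the averaged DMM against naive comparison, Atf3, a transcription factor of injured neurons, differed by -0.14 ± 0.28, and the chemokine Ccl2 and its receptor Ccr2 by 0.07 ± 0.11 and 0.08 ± 0.09. Tlr2 and Tlr4, receptors for microbial and danger signals, differed by 0.01 ± 0.07 and 0.15 ± 0.07. Aif1, a macrophage protein, differed by 0.09 ± 0.06 and Gfap, a glial filament, by -0.02 ± 0.07. Their adjusted p ran from 0.689 for Tlr4 to 0.989 for Tlr2. Against sham at 16 weeks Ccl2 differed by 0.22 ± 0.20 (adjusted p = 0.936). Calca had no probe set with that symbol alone, and Il1b and Tnf lay below the brightness limit, with means of 4.51 and 4.39. Tlr2 and Gfap, with means of 4.95 and 4.81, lay above that limit but below the negative control medians of all arrays. Their small differences therefore cannot show that expression was unchanged.

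Sham against naive mice asks what the operation does without the joint lesion. At 4 weeks, some macrophage genes were lower in sham than in naive mice. The naive arrays of this time had the highest macrophage mean of the 9 groups, at 7.001, beside 6.542 in sham mice. Naive mice at 8 and 16 weeks had 6.588 and 6.456. Cd68, a lysosomal protein of macrophages, fell by 0.74 ± 0.14, Mrc1, a mannose receptor, fell by 0.71 ± 0.14 and Csf1r fell by 0.56 ± 0.11 (adjusted p = 0.0411 for each). C1qc fell by 0.76 ± 0.15 (adjusted p = 0.0411) and Gpihbp1, which holds lipoprotein lipase on capillaries, fell by 0.53 ± 0.08 (adjusted p = 0.0185). With the nerve injury covariate Cd68 and Mrc1 were lost (adjusted p = 0.0643 and 0.0674). With the control probe set covariate C1qc, Csf1r and Mrc1 were lost (adjusted p = 0.0526, 0.0523 and 0.0526). Mycbp2, a ubiquitin ligase of neurons, rose by 0.40 ± 0.07 and Ago3, an RNA silencing protein, by 0.45 ± 0.09 (adjusted p = 0.0411 and 0.0412). The genes named here belong to 18 of largest difference that the naming rule gave. That rule takes only genes with no overlap between the groups, and the 18 held 4 ribosomal or translation factor pseudogenes.

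All 19 macrophage markers were lower, with a median of -0.45, where 3 fell over all genes and 15 adjusted over the list alone (camera adjusted p = 4.31e-10, fry adjusted p = 0.000725). The set had adjusted p = 0.165 with an estimated correlation. Fibroblast and meningeal markers were lower in 19 of 19 cases too, with a median of -0.44 (camera adjusted p = 0.0654), and extracellular matrix genes in 27 of 30, with a median of -0.33 (camera adjusted p = 0.0595). All 18 ribosomal protein genes were lower, with a median of -0.18, where 0 fell over all genes and 10 adjusted over the list alone (camera adjusted p = 7.15e-07, adjusted p = 0.167 with an estimated correlation). Pain ion channels had a median of 0.20, with 0 over all genes and 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 7.74e-07, adjusted p = 0.194 with an estimated correlation). Asic3, an acid-sensing channel, differed by 0.52 ± 0.11 (adjusted p = 0.0529). In all 67 genes passed, 10 higher and 57 lower, with 3229 at an unadjusted p under 0.05. The split turned under cyclic loess, to 79 higher and 35 lower, and quantile normalization gave 33 higher and 81 lower. Only 11 genes passed without sham replicate 1, 2 without sham replicate 3, 1 without naive replicate 2 and 0 without any other array of the 6 or with only the arrays compared.

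At 16 weeks, sham mice differed from naive mice mainly in sets of genes. Oxidative phosphorylation genes of the mitochondria were higher in 29 of 31 cases, with a median of 0.15 and 0 past over all genes or adjusted over the list alone (camera adjusted p = 1.82e-07, fry adjusted p = 0.0436). The list had adjusted p = 0.531 with an estimated correlation. Macrophage markers were higher in 19 of 19 cases, with a median of 0.23, 0 past over all genes and 1 adjusted over the list alone (camera adjusted p = 0.000288, adjusted p = 0.563 with an estimated correlation). They did not stand alone: 19 of 19 fibroblast and meningeal markers were higher with a median of 0.32 (camera adjusted p = 0.0262), and 15 of 15 myelinating Schwann cell markers with a median of 0.14 (camera adjusted p = 0.0211). Both had adjusted p = 0.967 with an estimated correlation, and without naive replicate 3 their camera adjusted p were 0.333 and 0.253. Non-peptidergic nociceptor markers, from a class of skin pain and itch neurons, were lower in 10 of 10 cases with a median of -0.24 (camera adjusted p = 0.000277, adjusted p = 0.711 with an estimated correlation). Neutrophil and marrow precursor markers had a median of 0.51, with Camp, an antimicrobial peptide, at 0.51 ± 0.15 (adjusted p = 0.234). That list had camera adjusted p = 0.000662 and adjusted p = 0.711 with an estimated correlation, and without sham replicate 2 its camera adjusted p was 0.386. The predicted gene Gm12481, named after its value was seen, was the single gene past the threshold, and it rose by 0.45 (adjusted p = 0.0179), with 2180 genes at an unadjusted p under 0.05. Sham and naive arrays of the same number deviated together at this time, and with the replicate number as a block 2 genes passed, 1 higher and 1 lower. The count was 76 without naive replicate 3, 4 without sham replicate 1, 2 without naive replicate 2, and 0 without naive replicate 1, sham replicate 2 or 3 or with only the arrays compared.

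Naive mice at 26 against 14 weeks of age ask what changes without surgery. Among the largest falls were genes of neuronal injury and regeneration and neuropeptides. Sprr1a, a protein of regenerating axons, went from 13.06 ± 0.05 to 5.90 ± 0.54, the neuropeptide Npy from 8.94 ± 0.71 to 5.46 ± 0.07, Nts, neurotensin, from 12.92 ± 0.19 to 9.75 ± 0.23 and Atf3 from 9.16 ± 0.46 to 6.72 ± 0.05 (n = 3 each). Their adjusted p were 0.00413, 0.00172, 0.00223 and 0.00241. The nerve injury response list had a median of -0.90, and 16 of its 23 members fell over all genes and 17 adjusted over the list alone (camera adjusted p = 1.99e-06, fry adjusted p = 0.00496). This was adjusted p = 0.673 with an estimated correlation.

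**Figure D3:**
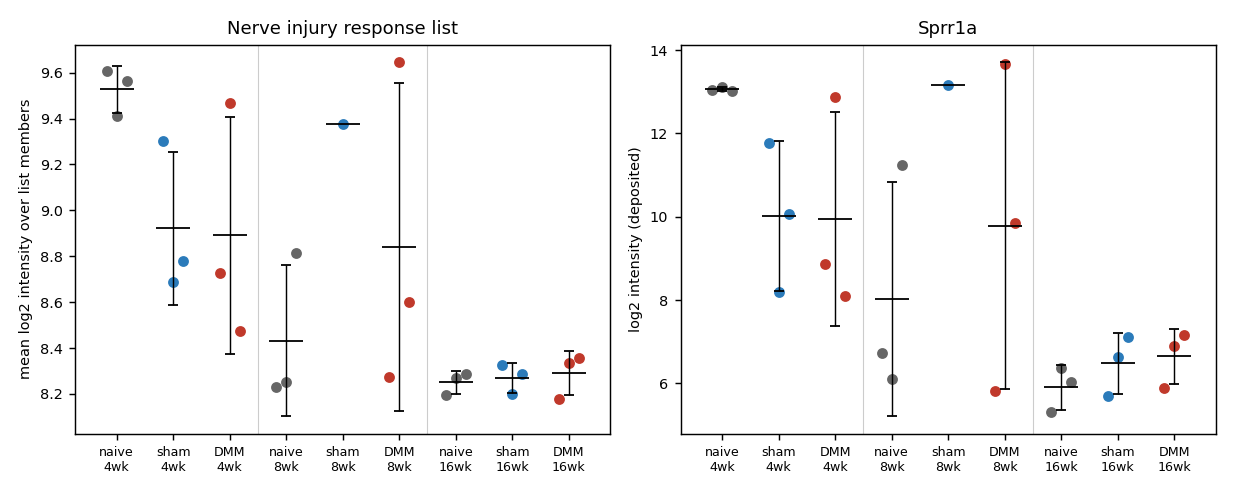
Mean log2 intensity over the 23 nerve injury response genes and log2 intensity of Sprr1a (vertical axes, which do not start at 0) in each array, by group and week. Points are arrays, long bars are group means and whiskers are SD (n = 3, except 1 sham array at 8 weeks). The list mean was 9.53 ± 0.10 in naive arrays at 4 weeks and 8.25 ± 0.05 at 16 weeks, and it spread within the groups at 8 weeks.

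Markers of some sensory neuron classes were higher in the older naive mice, while the sensory neuron list as a whole had a median of -0.02 (camera adjusted p = 0.847) and the nociceptor peptides one of -0.34 (camera adjusted p = 0.199). Sst, the peptide somatostatin, rose by 1.69 ± 0.35 (adjusted p = 0.00355), Th, tyrosine hydroxylase of touch neurons, by 1.45 ± 0.28 (adjusted p = 0.00204) and Mrgprb4, a receptor of skin sensory neurons, by 1.62 ± 0.39 (adjusted p = 0.00735). Of 10 non-peptidergic nociceptor markers 8 rose, over all genes and adjusted over the list alone, with a median of 0.49 (camera adjusted p = 2.95e-06, adjusted p = 0.519 with an estimated correlation). Macrophage markers had a median of -0.59, and 12 of 19 fell over all genes and 15 adjusted over the list alone (camera adjusted p = 2.95e-06). The same list had adjusted p = 0.519 with an estimated correlation, and fry gave adjusted p = 0.000146. Csf1r fell by 0.68 ± 0.11 (adjusted p = 0.000434). The fibroblast and meningeal list had a median of -0.44 (camera adjusted p = 0.606) and the extracellular matrix list one of -0.35 (camera adjusted p = 0.165), with 2 and 5 members lower over all genes. Pain ion channels went both ways, with 5 up and 2 down over all genes and 10 up and 2 down adjusted over the list alone. Their camera adjusted p was 0.000478, with adjusted p = 0.519 with an estimated correlation. Asic3 rose by 0.67 ± 0.11 (adjusted p = 0.000874), and Tmem100, a partner of pain channels, fell by 1.20 ± 0.27 (adjusted p = 0.00592). With the mean of the nerve injury list as a covariate Tmem100 was -0.30, Nts -0.47 and Sst 1.67 (adjusted p = 0.560, 0.463 and 0.0594), so these calls were lost.

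In all 3811 genes differed between the naive groups at 16 and 4 weeks, 1232 higher and 2579 lower, and 6723 had an unadjusted p under 0.05. Quantile normalization gave 962 higher and 4016 lower, the count was 2164 without naive replicate 1 at 16 weeks and 2282 without naive replicate 3 at 4 weeks, and any batch shared by a time point would fall in this comparison too.

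The change in DMM effect between 4 and 16 weeks was tested as an interaction. Against naive mice the predicted gene Gm12599, named after its value was seen, was the single gene past the threshold. Its DMM difference rose by 0.66 (adjusted p = 0.0401, with 2144 genes at an unadjusted p under 0.05). The difference of macrophage markers between DMM and naive mice was higher at 16 than at 4 weeks in 19 of 19 cases. The median of this change was 0.59, with 0 past over all genes and 12 adjusted over the list alone (camera adjusted p = 2.38e-10). The set had adjusted p = 0.141 with an estimated correlation, and fry gave adjusted p = 0.00438. In the same direction were fibroblast and meningeal markers, with a median of 0.42 (camera adjusted p = 0.0315, adjusted p = 0.798 with an estimated correlation), and extracellular matrix genes, with 0.33 (camera adjusted p = 0.0129, adjusted p = 0.797 with an estimated correlation). Without DMM replicate 2 at 16 weeks the camera adjusted p was 0.907 for each. Cx3cr1, the fractalkine receptor of macrophages, differed by 1.003 ± 0.213 (adjusted p = 0.204). The naive macrophage mean was 7.001 ± 0.137 at 4 weeks and 6.46 ± 0.07 at 16 weeks, the DMM mean was 6.84 ± 0.05 and 6.85 ± 0.14, and the sham mean was 6.54 ± 0.14 and 6.70 ± 0.09 (n = 3 each).

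Against sham mice no gene passed the interaction test in limma, and 1193 had an unadjusted p under 0.05. The difference of immediate early genes between DMM and sham mice was lower at 16 than at 4 weeks in 19 of 20 cases. The median of this change was -0.40, with 0 past over all genes and 3 adjusted over the list alone (camera adjusted p = 2.88e-05, adjusted p = 0.996 with an estimated correlation). Nr4a1, one of them, differed by -0.80 ± 0.24 (adjusted p = 0.732). Single arrays changed both counts: without DMM replicate 3 at 16 weeks 16 genes passed against naive mice, without DMM replicate 3 at 4 weeks or naive replicate 2 at 16 weeks 2 did, and 0 did without the others except naive replicate 2 at 4 weeks. With only the arrays compared 0 genes passed either interaction, and 1 passed against sham mice without DMM replicate 2 or 3 at 4 weeks or DMM replicate 2 at 16 weeks.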

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

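The tests of array quality, collection time, batch, neuron share and single arrays left out for a gene list were chosen only after results were seen.

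Clock genes stood apart between DMM and naive mice, with Arntl higher and Dbp, Per2 and Per3 lower. With the control probe set covariate 5 of 5 called members stayed past the threshold, at 1.08 for Arntl and -1.51 for Dbp, which argues against array quality. Of 14 members with a known phase, 13 moved as a shift in phase would move them, so an effect of DMM and another time of day at collection cannot be told apart. Chance is an unlikely source of the averaged count, though 100 splits cannot exclude it. Only 1 of them, the real one, reached the count, and the highest other split gave 4 genes. No biological explanation was tested, and no collection time is stated for the sham mice either. Arntl was 0.25 higher in sham than in naive mice at 16 weeks (limma adjusted p = 0.467). Dbp in sham against naive mice was -0.63 at 4 weeks (limma adjusted p = 0.16), with no overlap between the groups. At 4 weeks the clock list mean was 8.091 in naive, 7.899 in sham and 7.746 in DMM mice. At 16 weeks it was 8.217, 8.205 and 8.016.

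Nerve injury response genes were high in naive arrays at 4 weeks and in single arrays of other groups. With the control probe set covariate the list kept a median of -0.67 between naive mice at 16 and 4 weeks (fry adjusted p = 0.0283), which argues against array quality. At 4 weeks the list mean was 8.92 ± 0.33 in sham and 8.89 ± 0.52 in DMM mice beside 9.53 ± 0.10 in naive mice, and all sham arrays lay below all naive arrays, but fry adjusted p were 0.216 and 0.345. Age and a batch shared by a time point cannot be told apart. Neither would set arrays of the same group and time apart, yet the list mean ran from 8.476 to 9.469 in DMM arrays at 4 weeks. In DMM arrays it ran from 8.274 to 9.645 at 8 weeks and from 8.179 to 8.357 at 16 weeks. What sets these arrays apart was not tested. No biological explanation was tested, and the design gives no second batch per time.

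Macrophage markers were higher in DMM than in naive mice at 16 weeks. The median was 0.38 with the control probe set covariate (fry adjusted p = 0.0139), and the list stayed past the threshold by fry without each of the 6 arrays (adjusted p up to 0.0409). A lower share of neurons would raise all other cells alike, but 4 of 5 other lists had upper quartiles below the macrophage lower quartile of 0.27, and only the fibroblast and meningeal list, with a median of 0.49, did not. More sheath tissue in the DMM samples stays open. So does the operation itself: sham mice were 0.23 above naive mice, DMM mice were 0.14 above sham mice (adjusted p = 0.728 with an estimated correlation), and no biological explanation was tested.

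Splits of the 6 samples number only 10 for each comparison of 3 against 3, which is too few for a share under 0.05. The real count and the highest other were 1 and 1 for DMM against sham at 16 weeks, 2 and 0 for DMM against naive at 4 weeks, and 10 and 0 at 8 weeks. They were 67 and 0 for sham against naive at 4 weeks, 1 and 1 at 16 weeks, and 3811 and 0 for naive mice across time. For DMM against naive at 16 weeks they were 3 and 22, which points to a structure of the samples, and what it is was not tested. For the interaction against naive mice 4 of 100 splits reached the real count of 1, with 8 as the highest other. Where the real count was 0, in the interaction against sham mice (highest other 5) and in DMM against sham at 4 weeks (highest other 1), every split reaches it and the splits test nothing.

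The interaction between 16 and 4 weeks against naive mice was 0.66 for Gm12599. Higher list medians were 0.27 for ageing-associated immune genes, 0.43 for alarmins, 0.38 for class II antigen presentation, 0.15 for the cell cycle and 0.42 for fibroblasts. They were 0.59 for macrophages, 0.26 for Schwann cells, 0.10 for chemokines, 0.26 for complement, 0.33 for extracellular matrix and 0.18 for inflammatory cytokines. They were 0.53 for interferon-stimulated genes, 0.50 for nerve injury, 0.12 for oxidative phosphorylation and 0.23 for ribosomal proteins. Lower ones were -0.22 for low-threshold mechanoreceptors, -0.33 for non-peptidergic nociceptors, -0.30 for immediate early genes and -0.16 for pain ion channels. Against sham mice the medians were -0.23 for the glucocorticoid response, -0.40 for immediate early genes, 0.18 for interferon-stimulated genes, -0.13 for oxidative phosphorylation, 0.14 for pain ion channels and -0.13 for ribosomal proteins. None of these lists passed with an estimated correlation.

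Probe sets with no single gene symbol were left out of the gene counts. Of them 3 passed the threshold in DMM against naive mice at 8 weeks, 2 at 16 weeks and 2 in the averaged comparison.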

How the results depend on the processing

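The covariates of array quality and of nerve injury genes, and the leaving out of arrays for gene lists, were tests chosen only after results were seen, and the other settings were fixed before the data were examined. All settings fixed then were run. The lone sham array at 8 weeks is assumed to vary like the other groups, leaving out an array leaves arms of 2, and the counts of few genes near the threshold move with most settings. The cause was not tested except where the construction shows it.

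Without a filter on dim probe sets the count went from 0 to 2 for DMM against sham at 8 weeks, 10 to 5 for DMM against naive at 8 weeks, 67 to 3 for sham against naive at 4 weeks and 1 to 0 for the interaction against naive. Lists went from 11 to 20 for sham against naive at 4 weeks. With the filter at the 60th percentile it went from 0 to 3 for DMM against sham at 8 weeks, 10 to 21 and 3 to 8 for DMM against naive at 8 and 16 weeks, 67 to 163 for sham against naive at 4 weeks and 0 to 1 for the interaction against sham.

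Cyclic loess took the count from 0 to 3 for DMM against sham at 8 weeks, 10 to 5 for DMM against naive at 8 weeks, 67 to 114 for sham against naive at 4 weeks and 1 to 0 for the interaction against naive. Lists went from 8 to 13 for sham against naive at 16 weeks, and Ccr2 turned to 0.007 in DMM against sham at 16 weeks. Quantile normalization took the count from 0 to 1 and 0 to 3 for DMM against sham at 4 and 8 weeks, 10 to 5 for DMM against naive at 8 weeks, 67 to 114 for sham against naive at 4 weeks and 1 to 0 at 16 weeks.

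A fit of only the arrays compared has fewer residual degrees of freedom by construction. It took the count from 1 to 0 for DMM against sham at 16 weeks, from 2, 10 and 3 to 0 for DMM against naive at 4, 8 and 16 weeks, from 67 and 1 to 0 for sham against naive at 4 and 16 weeks and from 1 to 0 for the interaction against naive. The replicate block took it from 67 to 5 and 1 to 2 for sham against naive at 4 and 16 weeks. At 16 weeks 6 of 6 sham and naive arrays correlated best with their own number in the other group, and the block changed no list call. These groups were picked from the same data, so this is not evidence that the numbers pair the samples. At 4 weeks 2 of 6 correlated best with their own number, and under the block Cd68, Csf1r and C1qc had adjusted p = 0.0529 and Mrc1 0.0585. In DMM against naive at 16 weeks 3 of 6 did so, and Lyz1 had adjusted p = 0.0502.

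Array weights took the count from 0 to 7 and 0 to 1 for DMM against sham at 4 and 8 weeks, 2 to 20 and 3 to 17 for DMM against naive at 4 and 16 weeks, 67 to 628 and 1 to 8 for sham against naive at 4 and 16 weeks and 0 to 1 for the interaction against sham. The mean of a gene's probe sets took it from 10 to 18 for DMM against naive at 8 weeks. All probe sets took it from 3 to 5 for DMM against naive at 16 weeks, 1 to 0 for sham against naive at 16 weeks, 3811 to 7427 for naive mice across time and 1 to 0 for the interaction against naive.

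An unadjusted p under 0.05 with a 1.5-fold difference gave 39, 328 and 79 genes for DMM against sham at 4, 8 and 16 weeks and 49, 58 and 125 for DMM against naive. It gave 168 for sham against naive at 16 weeks, 974 for naive mice across time, and 227 and 173 for the interactions against naive and sham.

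With an estimated correlation the lists past the threshold went from 9, 9 and 9 to 0 for DMM against sham, from 11 and 14 to 0 and 16 to 2 for DMM against naive at 4, 8 and 16 weeks, and from 11 and 8 to 0 for sham against naive. They went from 10 to 0 for naive mice across time, 17 to 0 for the averaged comparison and 19 and 6 to 0 for the interactions. By fry there were 0, 0 and 0 lists for DMM against sham, 0, 1 and 4 for DMM against naive, 4 and 3 for sham against naive, 15 for naive mice across time beside 10 with the preset correlation, 1 for the averaged comparison and 4 and 0 for the interactions against naive and sham. Of 139 list calls, 137 were lost with an estimated correlation and 116 by fry.

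The control probe set covariate took the count from 67 to 10 for sham against naive at 4 weeks, 3811 to 2522 for naive mice across time and 1 to 0 for the interaction against naive, and Atf3 turned to 0.075 in DMM against sham at 16 weeks. The nerve injury covariate removes its own list by construction, so that list and its members are not reported under it. It took the count from 0 to 2 for DMM against sham at 8 weeks, 2 to 4 for DMM against naive at 4 weeks, 1 to 6 for sham against naive at 16 weeks, 3811 to 1851 for naive mice across time, 9 to 15 for the averaged comparison and 1 to 0 for the interaction against naive. Lists went from 9 to 16 and 9 to 14 for DMM against sham at 4 and 8 weeks and 14 to 8 for DMM against naive at 8 weeks. Ccr2 turned to 0.005 in DMM against naive at 4 weeks and Gfap to -0.019 at 8 weeks.

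With each array left out in turn the count ran from 0 to 2 for DMM against sham at 4 weeks and 0 to 11 at 16 weeks. It ran from 2 to 4, 4 to 120 and 1 to 325 for DMM against naive at 4, 8 and 16 weeks, 0 to 11 and 0 to 76 for sham against naive at 4 and 16 weeks and 2164 to 3083 for naive mice across time. It ran from 7 to 26 for the averaged comparison, 0 to 16 for the interaction against naive and 0 to 1 for that against sham. Lists ran from 9 to 15 and 3 to 14 for DMM against sham at 4 and 16 weeks, 5 to 13 and 9 to 18 for DMM against naive at 4 and 8 weeks, 6 to 15 for sham against naive at 4 weeks and 3 to 9 for the interaction against sham. The extracellular matrix list in DMM against sham at 16 weeks had a camera adjusted p from 3.02e-17 to 0.965, where it turned direction.

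Genes near 0 turned direction when arrays were left out. In the averaged comparison Atf3 ran from -0.357 to 0.028, Ccl2 from -0.026 to 0.133, Gfap from -0.051 to 0.036 and Tlr2 from -0.032 to 0.066. In DMM against naive, Ccr2 ran from -0.273 to 0.102 and Tlr2 from -0.157 to 0.031 at 4 weeks, and at 8 weeks Ccr2 ran from -0.048 to 0.191, Gfap from -0.071 to 0.127, Tlr2 from -0.263 to 0.033 and Tlr4 from -0.021 to 0.164. In DMM against sham, Atf3 ran from -0.543 to 0.472, Gfap from -0.062 to 0.047 and Tlr2 from -0.037 to 0.156 at 4 weeks. At 8 weeks Ccl2 ran from -0.124 to 0.327 and Ccr2 from -0.017 to 0.222, and at 16 weeks Aif1 ran from -0.032 to 0.093 and Ccr2 from -0.034 to 0.029.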

Other observations

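The tests with covariates were chosen only after results were seen, and the gene lists were fixed before the data were examined. Glucocorticoid response genes were lower in DMM than in naive mice over the 3 times, in 13 of 17 cases with a median of -0.13, 0 past over all genes and 8 lower adjusted over the list alone. Its camera adjusted p was 4.63e-05, with adjusted p = 0.387 with an estimated correlation. Per1, its member of smallest p (-0.547, limma adjusted p = 0.1115), is also in the clock list. This shift is therefore not independent of the clock shift. Neutrophil and marrow precursor markers were higher in 11 of 11 cases with a median of 0.17 (camera adjusted p = 5.29e-05, adjusted p = 0.387 with an estimated correlation). Their list mean was not higher in DMM than in sham mice at 4 weeks (5.32 in both) or 16 weeks (5.655 and 5.749). At 8 weeks it was 5.37 in DMM mice beside 5.282 in the lone sham array. These means lie near the negative control medians of the arrays (5.06 to 5.35).

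Cholesterol biosynthesis genes were higher in DMM than in naive mice at 8 weeks in 16 of 18 cases, with a median of 0.11 (camera adjusted p = 0.00165, adjusted p = 0.452 with an estimated correlation). Nociceptor peptides, the transmitters of pain neurons, had a median of 0.12 there (camera adjusted p = 0.0199, adjusted p = 0.452 with an estimated correlation), and B and plasma cell markers had a median of 0.17 (camera adjusted p = 0.0162, adjusted p = 0.452 with an estimated correlation). Each call was lost without a single array: without DMM replicate 2 the camera adjusted p was 0.637 for cholesterol biosynthesis and 0.640 for nociceptor peptides, without naive replicate 1 it was 0.155 and 0.210, without naive replicate 2 it was 0.0615 for nociceptor peptides, and without DMM replicate 1 it was 0.194 for B and plasma cells. Heat shock genes had a median of 0.03 in the averaged comparison, with 3 higher adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000875, adjusted p = 0.503 with an estimated correlation). Pericyte and smooth muscle markers had a median of 0.20 in DMM arrays over the lone sham array at 8 weeks. That array's list mean, 6.837, was the lowest of the 9 groups, and a single array cannot show a difference between DMM and sham mice.

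Of the 40 lists, 12 passed in no comparison with the preset correlation. The ranges of their medians were -0.07 to 0.13 for T and NK cells, -0.20 to 0.11 for adipocytes, -0.13 to 0.14 for cartilage and bone, -0.11 to 0.14 for endothelium and -0.13 to 0.30 for erythroid cells. They were -0.35 to 0.31 for mast cells, -0.12 to 0.09 for satellite glia, -0.07 to 0.04 for sensory neurons, -0.12 to 0.20 for skeletal muscle and -0.10 to 0.06 for spinal cord glia. They were -0.12 to 0.13 for neurotrophic factors and -0.06 to 0.02 for opioid and cannabinoid receptors.

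The smallest camera adjusted p among these 12 lists was 0.0529, for satellite glia. By fry a pair of them passed, both in naive mice at 16 against 4 weeks: adipocytes, with a median of -0.20 over 5 members (adjusted p = 0.000289), and satellite glia, with a median of -0.12 (adjusted p = 0.0356). Fabp7 rose without the other satellite glia markers as a set. Its list had a median of -0.02, while Fabp7 kept 0.66 in the averaged comparison with the control probe set covariate. That covariate bears on array quality only. Whether the rise reflects regulation of this gene, more glia or another time of day at collection was not tested. Over the 23 alternatives the adjusted p of Fabp7 was at most 0.000345, and which cells express Fabp7 was not tested.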
